A study of Rattus norvegicus with 8 samples.

How the data were processed

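The data are 8 1-colour microarrays of male rat lung, hybridised with Cy3-labelled cDNA from total RNA, per the labels. The labels give 4 groups of 2 samples each: normal air, 12 weeks of cigarette smoke, and smoke followed by EVs from human umbilical cord MSCs or by the MSCs, given into the trachea in week 13. They do not say that replicates are separate animals, so p values measure the spread between these samples, which may in part be technical. All arrays lie on 1 slide and were scanned in 1 scan; each group fills 1 column of the slide, so column and group cannot be told apart, and the row of an array is its replicate number.

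The deposited files are the output of Agilent Feature Extraction 10.7.3.1 for array design 074036, per the file headers, and hold intensity values per spot: the processed signal, which is background-subtracted and spatially detrended with small values replaced by a surrogate, and the median pixel of each spot and of its local background. The other flags per spot in the deposited files say whether it is well above background, saturated or an outlier, as 0 or 1. No spot was marked as saturated on any array. The deposited intensity values had not been normalized between arrays, per the file headers and their 75th percentiles, and any further processing by the authors is not given in the sources used here.

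Each array held 62976 spots, 4259 of them controls. Outlier spots were dropped, spots of a probe were averaged, and log2 of the processed signal minus the array's 75th percentile was the level of a probe. A probe was kept when well above background on both arrays of at least 1 group, which left 29612 of 45598 probes. Symbols were taken by matching RefSeq accessions without versions to a RefSeq gene table of assembly GRCr8, used for names only and without coordinates: 21215 probes matched, giving 16667 symbols, and 24383 kept the accession or probe name of the design. A gene with several kept probes (2688 symbols) was represented by the probe with the highest mean signal, and probes of a gene were called in opposite directions for 200 genes in smoke against naive, 122 in EV against smoke, 328 in MSC against smoke, 1 in EV against MSC and 0 in the comparisons of a treatment with naive. This gave 25097 features, 12729 of them with a symbol. Between 48.1% and 71.3% of probes were detected on an array, and replicates of a group correlated at 0.951 to 0.980 across probes.

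Differences were tested with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8, and figures with Python 3.11.15 and matplotlib 3.10.9), with 4 group means fitted over all 8 arrays (4 residual degrees of freedom, prior 3.58) and Benjamini-Hochberg adjustment at 0.05 in each of 6 comparisons. The 29 gene lists were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. The lists hold 567 genes of pathways, lung cell types and cell types of neighbouring tissue, 451 of them measured. Where a probe was not well above background on either array of a group, the ratio is a lower bound: the bright group's mean against, per array, the higher of the dim probe's signal and the lowest signal among probes well above background. Such a bound holds on the percentile scale only. All p values are 2-sided.

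The groups, tests, lists, the alternatives other than those named below and the rule for named genes were fixed before the data were examined. The rule took, for smoke against naive and each treatment against smoke, the 8 highest and 8 lowest log2 differences among called genes with a symbol whose groups did not overlap (4 and 4 for EV against MSC), the 3 members with the smallest p in the direction of each called list, and Cyp1a1, Nqo1, Mmp12, Il1b, Tnf, Cxcl1, Ccl2, Rela, Prkcz, Muc5ac, Scgb1a1 and Sftpc whatever their values in the first 3 comparisons. No probe was matched to Muc5ac. Some genes that the rule names are not reported here.

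The alternatives were normexp background correction with an offset of 50, for which the median spot signal stood in for the mean, quantile normalization, no filter on dim probes or a filter on all 8 arrays, the mean of a gene's probes, fits of the 2 groups compared, a trended and robust variance prior, array weights, the replicate number as a block, and each array left out in turn, where an arm of 1 array is assumed to vary like the other groups. Cyclic loess, scaling to the E1A spike-in controls and leaving out both smoke arrays were chosen after seeing the data. The spike-in scaling subtracted the mean log2 signal of 7 of the 10 E1A control probes, leaving out those with a mean log2 signal of 6 or less.

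The fit was tested on simulated data with 25097 features. Few of them were changed, 670 by 1 log2, 670 by 2 and 660 by 3 over the 10 simulations of a comparison. For smoke against naive it recovered 1.64% of changes of 1 log2, 40.0% of changes of 2 and 87.4% of changes of 3, for EV against smoke 0.746%, 41.6% and 88.0%, for MSC against smoke 0.597%, 41.8% and 86.8%, for EV against MSC 0.597%, 41.3% and 88.8%, for EV against naive 0.448%, 39.1% and 86.8%, and for MSC against naive 0.746%, 37.2% and 88.6%. In the real comparisons with smoke between 39.8% and 59.7% of features were called, which loosens the adjustment. The simulated rates thus do not describe recovery in those comparisons. A list shifted by 1 log2 was recovered in 10 of 10 simulations of each comparison. Over the 10 simulations of a comparison, between 0 and 3 other lists were called. Features were drawn independently of each other, so this does not show how the list test does where genes of a list vary together.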

Results

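Gene expression was measured on 8 1-colour rat arrays, each with RNA from male rat lung. The labels give 4 groups of 2 samples. Naive rats breathed normal air, and smoke-exposed rats received 12 weeks of cigarette smoke. In the other groups smoke was followed by mesenchymal stem cells (MSCs) from human umbilical cord or by the extracellular vesicles (EVs) that such cells release. The 75th percentile of signal was 568 and 362 on the naive arrays, 3235 and 2677 on the smoke arrays, 762 and 483 on the EV arrays and 246 and 256 on the MSC arrays. The geometric mean of the smoke arrays was 6.49 times that of the naive arrays. The control probes for the E1A spike-in RNAs of the array kit stood at 0.831 times their naive signal on the smoke arrays. All levels are log2 signals relative to each array's 75th percentile, so every direction is relative to the other probes of the same array. On this scale the median of all 25097 features lay at -0.62 in smoke against naive, 0.55 in EV against smoke and 0.74 in MSC against smoke. It lay at -0.28 in EV against MSC, -0.06 in EV against naive and 0.23 in MSC against naive. With scaling to the spike-in controls, chosen after seeing the data, the same medians were 2.34, -1.93, -3.28, 1.26, 0.42 and -0.83. Shifts of gene lists are given relative to the median of the named genes. The number of arrays limits the precision of every value.

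**Figure D1:**
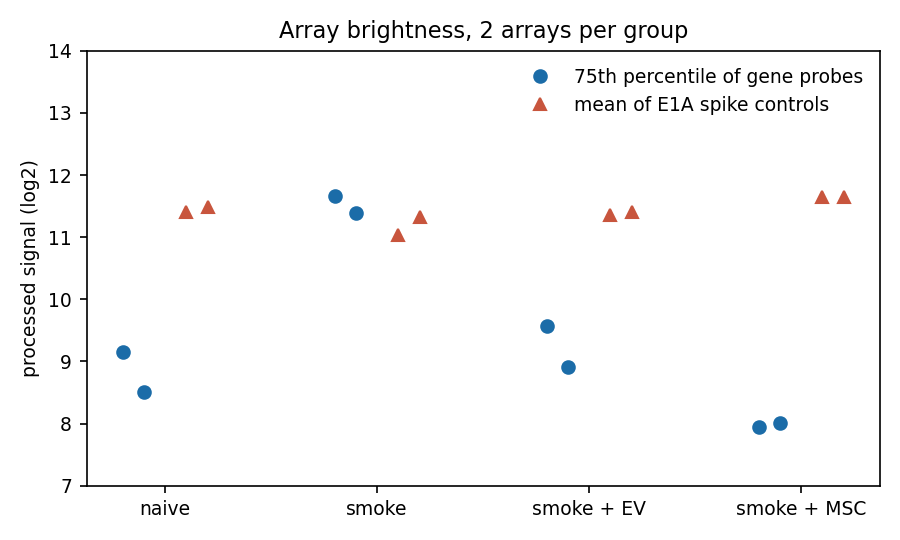
Log2 processed signal of each array, by group (2 arrays each), as the 75th percentile of gene probes (circles) and the mean of the E1A spike-in controls (triangles). The smoke arrays stand at 11.66 and 11.39 for gene probes, above the other 6 arrays, while the spike-in controls lie between 11.03 and 11.65 on all 8.

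The first comparison asked what 12 weeks of smoke changed in the lung. Rela, which encodes the p65 subunit of NF-kB, was higher in smoke-exposed than naive lung, with a log2 difference of 2.45 (SE 0.30, adjusted p = 0.00222). The neutrophil-attracting chemokine gene Cxcl1 was higher at 2.78 (SE 0.33, adjusted p = 0.00217). The alarmin gene Il33 rose, at 2.32 (SE 0.32, adjusted p = 0.00244), and so did the macrophage growth factor gene Csf1, at 1.96 (SE 0.46, adjusted p = 0.0121), though its other probe stood at 0.11 and the mean of both, 1.03, did not pass (adjusted p = 0.161). Sftpc, which encodes surfactant protein C of alveolar type 2 cells, was lower on this scale, at -2.23 (SE 0.36, adjusted p = 0.00365). Its difference turned to 0.74 with scaling to the spike-in controls, and its call was lost under cyclic loess, at -0.80. These adjusted p values come from limma with 2 arrays per group.

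Of the other genes fixed beforehand, none passed limma's threshold. The aryl hydrocarbon receptor target Cyp1a1, not well above background in naive lung, was brighter in smoke by at least 2.15-fold (adjusted p = 0.0646) without passing, and its fitted difference turned to -0.67 under normexp. The cytokine gene Il1b stood at -1.12 (SE 0.42, adjusted p = 0.0616), turning to 1.84 with scaling to the spike-in controls, and Tnf at 1.02 (SE 0.39, adjusted p = 0.0624). The others were Nqo1 (0.60), Mmp12 (-1.63), Ccl2 (0.78), Prkcz (-0.28) and Scgb1a1 (-1.05), with adjusted p from 0.199 to 0.415, of which Mmp12, Prkcz and Scgb1a1 turned to 1.33, 2.68 and 1.91 with scaling to the spike-in controls. Ccl2 turned to -0.95 under normexp, the other probe of Prkcz stood at 1.65, and Prkcz turned to 0.099 and Scgb1a1 to 0.039 under cyclic loess. Single naive arrays set the direction of 2 of these genes: Mmp12, at -2.47 and -6.61 on the naive arrays, turned to 0.44 without replicate 1 and passed at -3.71 without replicate 2, and Ccl2 turned to -0.028 without replicate 2. Muc5ac had no matched probe.

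Of the 29 fixed gene lists, 7 were shifted upward in smoke-exposed lung by limma's camera test with a preset correlation. In the cytokine and chemokine list 7 of 18 measured members rose and 2 fell (9 and 3 adjusted over the list alone). Its median lay 1.58 log2 above the named genes (camera adjusted p = 0.0143, and adjusted p = 0.699 with an estimated correlation). In the NF-kB list 6 of 16 measured members rose and 0 fell (5 and 0 adjusted over the list alone), with Nfkbib at 1.51 and Traf2 at 2.51, the latter detected on 1 of the 2 naive arrays (camera adjusted p = 0.0325, and adjusted p = 0.699 with an estimated correlation). In the macrophage list 5 of 22 measured members rose and 0 fell (4 and 0 adjusted over the list alone), with the chitinase-like gene Chi3l1 at 2.38 (camera adjusted p = 0.0307, and adjusted p = 0.699 with an estimated correlation). In the neutrophil list 4 of 13 measured members rose and 1 fell (4 and 1 adjusted over the list alone), with the lipocalin gene Lcn2 at 1.63 (camera adjusted p = 0.0306, and adjusted p = 0.897 with an estimated correlation). In the cytotoxic cell list 4 of 12 measured members rose and 1 fell (4 and 1 adjusted over the list alone), with the granzyme gene Gzmb at 2.82 and the perforin gene Prf1 at 2.45 (camera adjusted p = 0.0307, and adjusted p = 0.897 with an estimated correlation).

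In the extracellular matrix list 8 of 20 measured members rose and 2 fell (10 and 4 adjusted over the list alone), with the crosslinking enzyme gene Loxl1 at 3.41 and Sparc at 2.30 (camera adjusted p = 0.0193, and adjusted p = 0.699 with an estimated correlation). In the class II antigen presentation list 6 of 14 measured members rose and 1 fell (6 and 1 adjusted over the list alone), with RT1-Da at 2.31 and RT1-Db1 at 1.71 (camera adjusted p = 0.0143, and adjusted p = 0.934 with an estimated correlation). RT1 genes form a family of close copies, so the value of a single RT1 gene is uncertain. The named list members had limma adjusted p from 0.00295 to 0.0307. The same arrays were the bright ones, at 6.49 times the naive signal. None of the 7 calls held with quantile normalization (lowest camera adjusted p 0.0578) or with cyclic loess (0.0560), which was chosen after seeing the data, or with scaling to the spike-in controls (0.0596). The macrophage and neutrophil calls were lost under normexp (0.121 and 0.182), the macrophage and cytotoxic cell calls with the mean of a gene's probes (0.0612 and 0.0536), and 5 calls with probes detected on all 8 arrays (up to 0.208). Leaving out naive replicate 1, naive replicate 2 or smoke replicate 1 ended 3, 5 and 3 of the calls (highest adjusted p 0.103, 0.154 and 0.268). By limma's fry test the cartilage list alone passed, as lower (adjusted p = 0.0484). In it 1 of 7 members rose and 4 fell, or 1 and 5 adjusted over the list alone, which turned to 4 rising, 0 falling and a median of 1.22 with scaling to the spike-in controls.

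The genes with the largest differences were of other kinds. RT1-CE5, a class I histocompatibility gene, was lower at -9.12 (SE 0.31, adjusted p = 0.000112). The testis cytochrome c gene Cyct was lower at -6.19 (SE 0.69, adjusted p = 0.00216) and Rup2 at -7.17 (SE 2.51, adjusted p = 0.0478), both detected on 1 of the 2 smoke arrays. Not well above background in smoke-exposed lung, and so lower by a bound only, were Cyp4a2 (at least 42.0-fold), Or9q1 (at least 21.1-fold), Akr1c2 (at least 20.0-fold), Cpamd8 (at least 24.7-fold) and Mrgprb13 (at least 13.9-fold), with limma adjusted p from 0.00216 to 0.0188. Mrgprb13 was detected on 1 of the 2 naive arrays. The bounds on these lower genes hold on the percentile scale only, and fitted differences with scaling to the spike-in controls fell short of them. There Cyp4a2, Or9q1, Akr1c2, Cpamd8 and Mrgprb13 stood at -2.77, -3.34, -3.50, -2.74 and -2.92 log2. Cyp4a2 encodes a fatty acid hydroxylase and Or9q1 an olfactory receptor. Not well above background in naive lung, and so higher by a bound, were Tmem252 (at least 20.7-fold), Plrg1 (at least 17.7-fold), Oas1k (at least 13.53-fold), Grap (at least 6.69-fold), Srpx2 (at least 5.15-fold) and Nhlrc3 (at least 4.97-fold), with adjusted p from 0.00216 to 0.0145. The defensin genes Defa5 (4.95) and Np4 (4.59) were higher, with adjusted p from 0.0154 to 0.0220 by limma. They are close copies, so their values are uncertain, and each was detected on 1 of the 2 naive arrays. As a class, 136 of 210 olfactory, vomeronasal and taste receptor genes fell and 0 rose, which turned to 6 falling and 136 rising with scaling to the spike-in controls. Their median lay -1.38 log2 from genes of like naive level. Of 96 control probes for ERCC sequences, which are synthetic and not rat, 8 were well above background on both naive arrays, and all 8 were lower on both smoke arrays, by a median of -2.92 log2. In signal itself, before scaling, their median difference was -0.22. The largest were at ERCC-00018_67, at -3.25 and -3.59 on the naive arrays and -10.08 and -8.99, not well above background, on the smoke arrays, and ERCC-00113_271, at 0.16 and 0.16 against -6.81 and -5.26.

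By limma with Benjamini-Hochberg adjustment, 11925 features (47.5%) were called, 3037 higher and 8888 lower. The split depended on the scaling. Of the calls, 25.5% were higher, against 46.6% with quantile normalization, 49.3% with cyclic loess, 10.4% with normexp and 99.4% with scaling to the spike-in controls. Under the last, 8062 of the 11925 called features changed direction. Without smoke replicate 1 the count was 4376, and 16 of the 38 named genes called lost their call (highest adjusted p 0.250), among them Lcn2, Nfkbib, Traf2, Csf1, Defa5 and Np4. Without naive replicate 1 and naive replicate 2, 6 and 7 named genes lost theirs (0.105 and 0.218), and without smoke replicate 2, 3 did (0.0800). Rup2, at -5.32 and 2.99 on the naive arrays, kept its call in 5 of 17 other settings. It lost it with any 1 of the treated arrays left out (up to 0.0648), without naive replicate 2 (0.218), without smoke replicate 1 (0.250), without the filter on dim probes (0.0653), with the mean of a gene's probes, in a fit of the 2 groups only (0.0807), with the trended and robust prior (0.0590), with cyclic loess (0.0858) and with quantile normalization. Srpx2, Nhlrc3, Grap, Mrc1 and Csf3r lost theirs under normexp (up to 0.902, for Csf3r), where Mrc1 and Csf3r turned. Quantile normalization also ended the calls of Cpamd8 and Sftpc. The Sftpc probe ranked 1 of 45598 by signal on every naive, smoke and EV array, so that method sets its differences among them to 0 and carries no information on them.

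**Figure D2:**
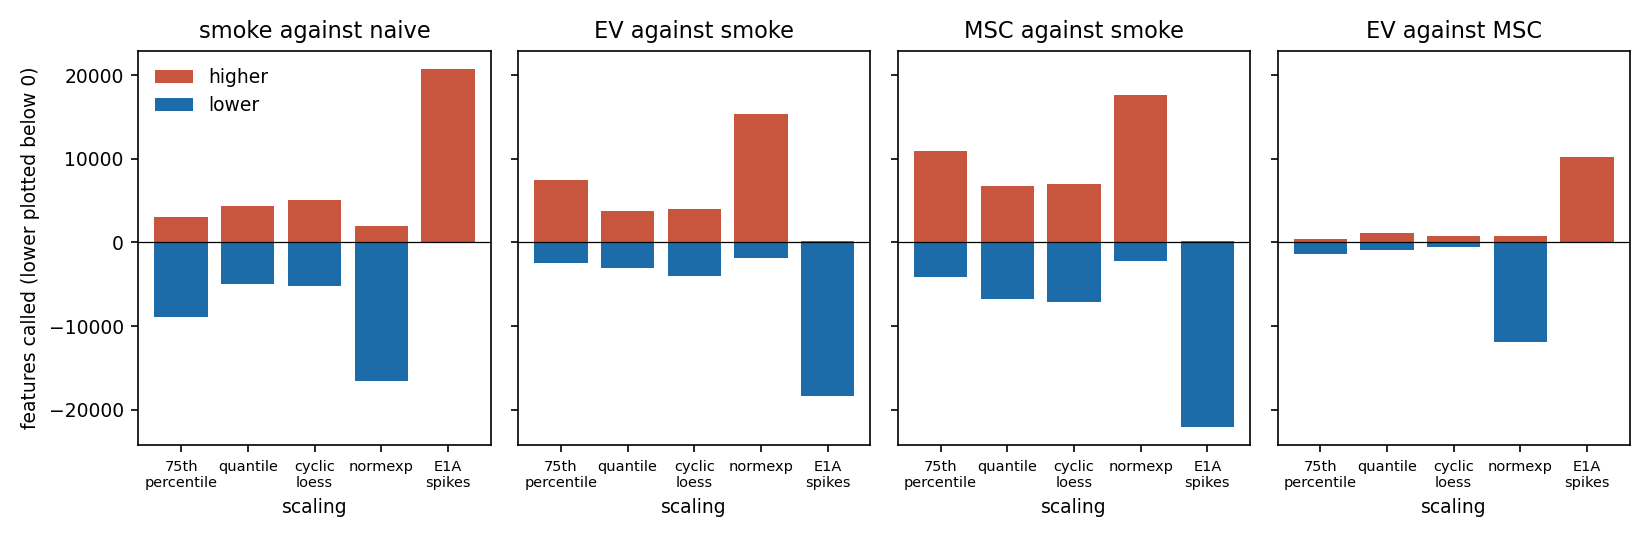
Number of features called by limma in 4 comparisons under 5 scalings, higher above 0 and lower below 0. In smoke against naive the calls go from 3037 higher and 8888 lower under the 75th percentile to 20759 higher and 129 lower under the E1A spike-in controls.

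The second comparison asked what EVs given after smoke changed. Relative to untreated smoke-exposed lung, Rela was lower at -2.18 (SE 0.30, adjusted p = 0.00433). Cxcl1 was lower at -1.80 (SE 0.33, adjusted p = 0.00714) and Il33 at -1.81 (SE 0.32, adjusted p = 0.00619). Sftpc was higher on this scale at 1.86 (SE 0.36, adjusted p = 0.00837), but turned to -0.62 with scaling to the spike-in controls, and its call was lost under cyclic loess, at 0.64 (adjusted p = 0.148). In the interferon response list 2 of 17 measured members rose and 8 fell (3 and 8 adjusted over the list alone), with Ifi27 (-2.63), Oas1a (-2.38) and Usp18 (-3.24). The list had camera adjusted p = 0.0464, and adjusted p = 0.956 with an estimated correlation. In the cytokine list 1 of 18 measured members rose and 5 fell (1 and 5 adjusted over the list alone), with camera adjusted p = 0.0464, and adjusted p = 0.956 with an estimated correlation. Its member Cxcl10 stood at -2.18, on 1 of the 2 EV arrays, and turned to 0.071 under normexp. In the cytotoxic cell list 1 of 12 measured members rose and 5 fell (1 and 6 adjusted over the list alone), with Gzmb (-2.62) and Prf1 (-2.02). The list had camera adjusted p = 0.0464, and adjusted p = 0.956 with an estimated correlation. Its member Klrk1 stood at -2.00, on 1 of the 2 EV arrays, and turned to 0.48 under normexp. The named list members had limma adjusted p from 0.00463 to 0.0295. The smoke arrays, on which these differences rest, were the bright ones.

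Among the largest differences after EVs, RT1-CE5 (9.25), Cyct (6.82), Arid3a (6.10), Evi5 (6.00), Or52e8b (5.61) and Pgm5 (5.59) were higher, with limma adjusted p from 0.000100 to 0.00606. The 3 probes of Evi5 ranged from -1.21 to 6.00 and the other probe of Pgm5 stood at -0.011, and the means of their probes were 2.25 and 2.79. Cyct and Or52e8b were detected on 1 of the 2 smoke arrays. Higher by a bound were Or9q1 (at least 20.9-fold) and Cyp4a2 (at least 43.2-fold), with adjusted p from 0.00277 to 0.00279. With scaling to the spike-in controls their fitted differences fell short of these bounds, at 3.81 and 3.29 log2. The endothelial co-receptor gene Eng was lower at -4.57 (SE 0.46, adjusted p = 0.00301) and the fibrinogen gamma chain gene Fgg at -4.29 (SE 0.82, adjusted p = 0.00778). Grina stood at -4.46 (SE 0.58, adjusted p = 0.00402) and RT1-O1 at -4.21 (SE 1.33, adjusted p = 0.0392). Lower by a bound were Rnase3 (at least 12.5-fold), Plrg1 (at least 25.7-fold), Alg2 (at least 5.42-fold) and Pef1 (at least 4.81-fold), with adjusted p from 0.00412 to 0.0176. Of the genes fixed beforehand, Nqo1 (-0.99), Ccl2 (-1.18), Il1b (0.66), Scgb1a1 (0.60), Cyp1a1 (0.41), Prkcz (0.26) and Tnf (-0.20) did not pass, with adjusted p from 0.0751 to 0.812 by limma, of which Il1b, Scgb1a1, Cyp1a1 and Prkcz turned to -1.82, -1.88, -2.07 and -2.22 with scaling to the spike-in controls. Ccl2 and Tnf turned under normexp and Scgb1a1, Cyp1a1 and Prkcz under cyclic loess, and the other probe of Prkcz stood at -1.72. The Cyp1a1 value averages EV arrays at -6.31 and -1.69, and stood at -1.90 without EV replicate 2 and 2.72 without EV replicate 1, where it passed (adjusted p = 0.0324). For Mmp12 no fold could be given, because of signal near background.

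In all, limma called 9993 features, 7493 higher and 2500 lower. The share of higher calls was 74.98%, against 54.8% with quantile normalization, 49.6% with cyclic loess, 89.1% with normexp and 1.002% with scaling to the spike-in controls. The count was 1860 without smoke replicate 1, 5415 without EV replicate 1 and 2263 without EV replicate 2. Without smoke replicate 1, 10 of the 27 named genes called lost their call (highest adjusted p 0.169), and without EV replicate 2, 11 did (0.171), in both cases Il33, Cxcl1, Cxcl10, Gzmb, Prf1, Klrk1 and Sftpc among them. Without EV replicate 1, Alg2, RT1-O1 and Prf1 lost theirs (0.122), and without smoke replicate 2, RT1-O1 and Klrk1 (0.113). Under normexp Pef1, Alg2, Cxcl10 and Klrk1 lost theirs (up to 0.841), and with quantile normalization RT1-O1 and Sftpc, the latter again by its rank. None of the 3 list calls held with quantile normalization (0.123), cyclic loess (0.105), scaling to the spike-in controls (up to 0.256) or the mean of a gene's probes (0.0572), nor without smoke replicate 1 (0.121 to 0.172), either naive array (0.0521) or either MSC array (0.0638). The cytokine call was lost without EV replicate 1 (0.0721) and the cytotoxic cell call without EV replicate 2 (0.0637). By fry the cartilage list alone passed, as higher (adjusted p = 0.0481), with 3 of 7 members rising and 0 falling, or 5 and 0 adjusted over the list alone, which turned to 0 rising, 1 falling and a median of -1.05 with scaling to the spike-in controls.

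The third comparison set lung treated with the MSCs against untreated smoke-exposed lung. Cxcl1 was lower at -3.90 (SE 0.33, adjusted p = 0.000231) and Rela at -2.78 (SE 0.30, adjusted p = 0.000357). The cytokine gene Il1b was higher on this scale at 1.19 (SE 0.42, adjusted p = 0.0424) and Tnf at 1.10 (SE 0.39, adjusted p = 0.0405). The other probe of Tnf stood at -0.94, and the mean of both, 0.078, did not pass (adjusted p = 0.927). With scaling to the spike-in controls both turned, to -2.83 and -2.92. Sftpc was higher at 1.93 (SE 0.36, adjusted p = 0.00300), but lower at -1.07 after quantile normalization and -2.09 with scaling to the spike-in controls, and passed in both. Cyp1a1 was lower by at least 1.45-fold (adjusted p = 0.0977) without passing, and turned under normexp. Nqo1 (-0.74), Prkcz (-0.64), Ccl2 (0.55) and Scgb1a1 (0.43) did not pass either, with adjusted p from 0.0749 to 0.582 by limma, and Ccl2 and Scgb1a1 turned after quantile normalization and, to -3.47 and -3.59, with scaling to the spike-in controls. Both also turned without MSC replicate 2, to -0.21 and -0.54, against 1.31 and 1.39 without MSC replicate 1. For Mmp12 no fold could be given.

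No list passed camera in MSC against smoke. At an unadjusted p under 0.05 camera counted 7 lists, or 0 with an estimated correlation, and 2 passed fry after adjustment. The smallest camera adjusted p, 0.119, was shared by 5 lists. In the cytokine list 4 of 18 measured members rose and 8 fell (4 and 8 adjusted over the list alone), and in the interferon list 5 of 17 measured members rose and 9 fell (5 and 9 adjusted over the list alone). In the NF-kB list 1 of 16 measured members rose and 5 fell (1 and 5 adjusted over the list alone), and fry called it as lower (adjusted p = 0.0405). In the neutrophil list 2 of 13 measured members rose and 4 fell (1 and 3 adjusted over the list alone), and in the cytotoxic cell list 1 of 12 measured members rose and 7 fell (1 and 7 adjusted over the list alone). In these 5 lists, in the order given, rising and falling members were 2 and 11, 2 and 11, 0 and 8, 1 and 8 and 1 and 8 with quantile normalization and 0 and 15, 0 and 17, 0 and 16, 0 and 13 and 0 and 11 with scaling to the spike-in controls, where those that rose no longer did. By fry the cartilage list passed as higher (adjusted p = 0.0238), where 5 of 7 measured members rose and 1 fell (5 and 1 adjusted over the list alone), which turned to 0 rising, 6 falling and a median of -1.77 with scaling to the spike-in controls. In the cardiac muscle list 9 of 14 measured members rose and 0 fell (10 and 0 adjusted over the list alone), but 1 rose and 0 fell with quantile normalization, and with scaling to the spike-in controls 1 rose and 3 fell. It held the cardiac myosin gene Myh6 at 7.81 (SE 2.89, adjusted p = 0.0478). Myh6 was detected on 1 of the 2 smoke arrays, and its levels on the 2 MSC arrays had an SD of 4.51.

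Among the largest differences after MSCs, RT1-CE5 (9.50), Cyct (8.97), Evi5 (8.20), Or52e8b (8.06), Ephb2 (8.04) and Arid3a (7.64) were higher, with limma adjusted p from 8.21e-05 to 0.000484. The 3 probes of Evi5 ranged from -3.64 to 8.20, with a mean of 2.37. Cyct and Or52e8b were detected on 1 of the 2 smoke arrays. Or9q1 was higher by at least 104-fold (adjusted p = 0.000187). With scaling to the spike-in controls its fitted difference fell short of this bound, at 4.58 log2. Lower by a bound were Defa5 (at least 35.1-fold), Np4 (at least 29.3-fold), Tmem252 (at least 13.99-fold), Gucy1b1 (at least 12.2-fold), Fundc2 (at least 13.0-fold), Slfn4 (at least 7.88-fold) and Vav3 (at least 13.47-fold), with adjusted p from 0.000215 to 0.0112. In all, limma called 14991 features, 10870 higher and 4121 lower. The share of higher calls was 72.5%, against 50.03% with quantile normalization, 49.2% with cyclic loess, 89.0% with normexp and 0.885% with scaling to the spike-in controls. Of the 21 named genes called, Myh6 lost its call without either naive array, either smoke array or MSC replicate 2. Il1b lost it without either naive array, smoke replicate 2, either EV array or MSC replicate 2, and Tnf without either smoke array, either EV array or MSC replicate 1. Np4 lost it without smoke replicate 1 or MSC replicate 1. In these settings the highest adjusted p of the named genes ranged from 0.0600 to 0.257. Myh6, Il1b and Tnf also lost theirs with quantile normalization (up to 0.142), where Sftpc passed in the other direction (-1.07, adjusted p = 0.00798), Myh6, Il1b, Tnf and Sftpc with cyclic loess (up to 0.698), and Slfn4 under normexp (0.202). Myh6 and Il1b lost theirs with array weights (up to 0.110) and with the replicate number as a block (up to 0.0581), Il1b and Tnf in a fit of the 2 groups only (up to 0.0937), and Myh6 with scaling to the spike-in controls (0.117).

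**Figure D3:**
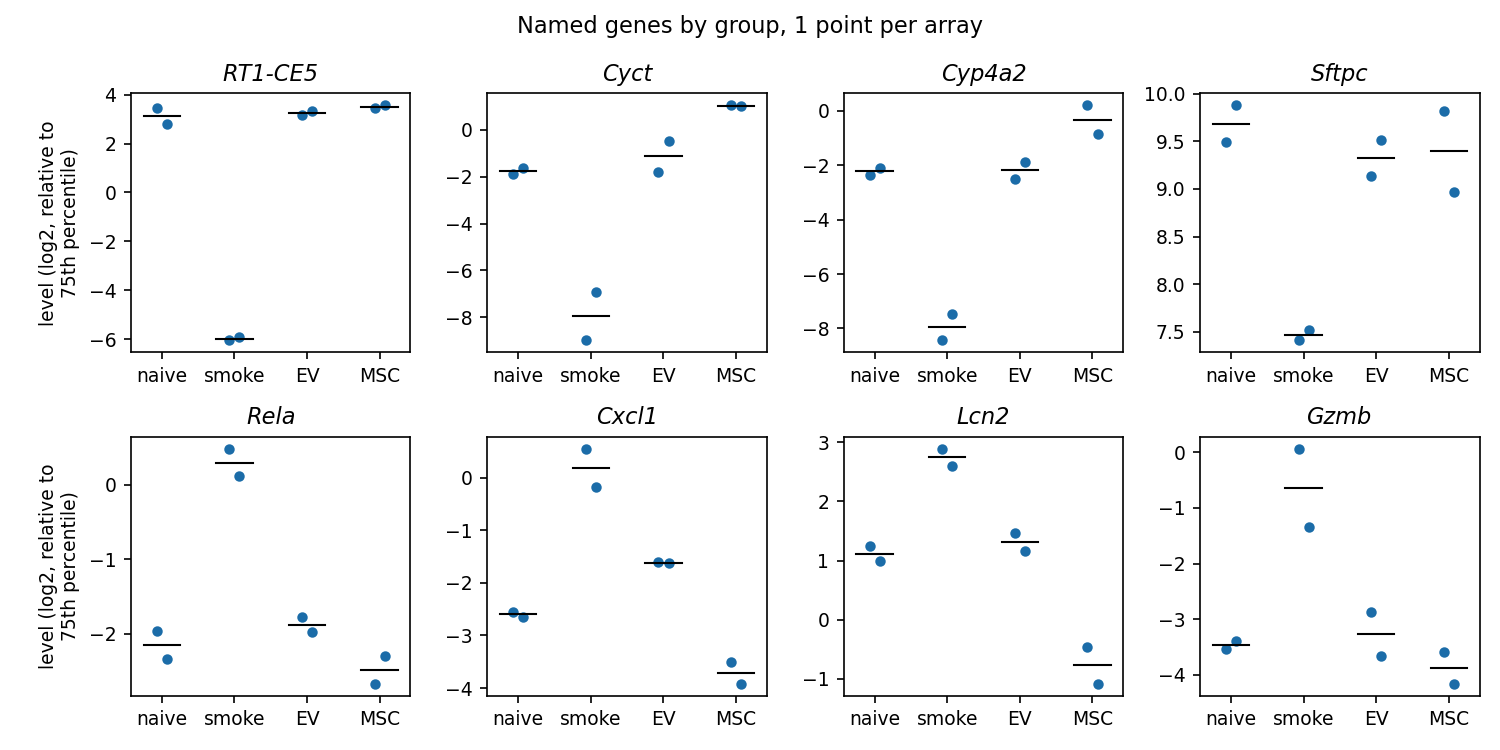
Level of 8 of the named genes on each array (circles, 2 per group) with the group mean (lines), as log2 signal relative to the array's 75th percentile. RT1-CE5, Cyct, Cyp4a2 and Sftpc are lowest on the smoke arrays and Rela, Cxcl1, Lcn2 and Gzmb highest, with Sftpc alone of these turning its direction under scaling to the spike-in controls.

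Both treatments ran against the smoke difference. Of the 3037 features that rose with smoke, 2185 fell after EVs and 2598 after MSCs, where independent lists of these sizes would share 303 and 499. Of the 8888 that fell, 6766 rose after EVs and 8307 after MSCs, against 2654 and 3850. Across genes, which are not independent replicates, the smoke and EV differences correlated at -0.925 with a covariance of -1.67. The smoke and MSC differences correlated at -0.911 with a covariance of -2.28. All of these share the smoke arrays, and 100 simulations of unchanged groups gave mean correlations of -0.500 and mean covariances of -0.11. Beyond the shared noise estimated from the fit, the excess covariance was -1.53 for EVs and -2.14 for MSCs. With 1 smoke array for the smoke difference and the other for the treatment difference, covariances were -1.57 and -1.57 for EVs and -2.21 and -2.16 for MSCs. Part of the overlaps and correlations may come from the shared smoke arrays.

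The fourth comparison tested EV against MSC treatment directly. Cxcl1 was higher after EVs than after MSCs by 2.10 log2 (limma adjusted p = 0.0369). In the neutrophil list 1 of 13 measured members rose and 0 fell (2 and 0 adjusted over the list alone), namely Lcn2 at 2.09 (SE 0.32, adjusted p = 0.0369). The list had camera adjusted p = 0.0364, and adjusted p = 0.922 with an estimated correlation. The calprotectin gene S100a8 stood at 1.89 (SE 0.47, adjusted p = 0.0528); it did not pass. In the mast cell list 0 of 13 measured members rose and 3 fell (0 and 4 adjusted over the list alone), with camera adjusted p = 0.0364, and adjusted p = 0.922 with an estimated correlation. The mast cell protease genes Mcpt1 (-2.56), Tpsb2 (-2.01) and Cpa3 (-2.01) were lower after EVs (limma adjusted p from 0.0412 to 0.0496), with Mcpt1 on 1 of the 2 EV arrays. Mcpt1, Tpsb2 and Cpa3 did not pass with scaling to the spike-in controls (adjusted p = 0.227, 0.543 and 0.521), and with the replicate number as a block, which is the row of the slide, Mcpt1, Cpa3 and the T cell gene Cd3e did not (up to 0.0638). In the T cell list 0 of 17 measured members rose and 1 fell (0 and 5 adjusted over the list alone), with Cd3e at -1.64 (SE 0.38, adjusted p = 0.0484). The list had camera adjusted p = 0.0364, and adjusted p = 0.922 with an estimated correlation. In the alveolar type 2 list, shifted upward after EVs, 0 of 15 measured members rose and 0 fell (0 and 0 adjusted over the list alone), with Slc34a2 at 1.61 (camera adjusted p = 0.0377, and adjusted p = 0.922 with an estimated correlation). Its median level was 2.67 and 3.14 on the EV arrays, 3.21 on MSC replicate 1 and 2.06 on MSC replicate 2. Only MSC replicate 2 lay below the EV arrays. In the immediate early list, shifted downward, 0 of 18 measured members rose and 0 fell (0 and 0 adjusted over the list alone), with Egr3 at -1.39 (camera adjusted p = 0.0364, and adjusted p = 0.922 with an estimated correlation). Scaling to the spike-in controls shifts all genes of a comparison alike, so a list's place relative to the other genes could not change. The camera adjusted p of the mast cell, T cell and immediate early lists there (6.25e-05, 0.00168 and 6.32e-07) are thus no separate support. On that scale the medians of these lists were 0.41, 0.59 and 0.21, Egr3 turned to 0.15 and Cd3e did not pass (limma adjusted p = 0.884). Rising and falling members were then 1 and 0, 0 and 0 and 1 and 0 in these lists, 11 and 0 in the neutrophil list and 12 and 0 in the alveolar type 2 list, against 0 and 0, 0 and 0, 0 and 0, 2 and 0 and 4 and 0 with quantile normalization.

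By size, Gucy1b1 (at least 3.36-fold), Gpr158 (at least 2.94-fold), Gpm6a (at least 3.29-fold) and C2cd2l (at least 3.05-fold) were higher after EVs by a bound, with limma adjusted p from 0.0314 to 0.0390. Each of them turned to a value between -0.12 and -0.035 under normexp, and the other probe of C2cd2l stood at 0.20. Suv39h2 (-3.53), Ptprv (-3.03) and Rnf43 (-3.00) were lower, with adjusted p from 0.0369 to 0.0379, and Rnf43 was on 1 of the 2 EV arrays. Ptprv and Rnf43 did not pass with scaling to the spike-in controls (0.0600 and 0.0511). Slc17a6 was lower by at least 5.12-fold (adjusted p = 0.0434). With scaling to the spike-in controls its fitted difference fell short of this bound, at -1.80 log2. In all, limma called 1791 features, 451 higher and 1340 lower, with 7776 at an unadjusted p under 0.05. The share of higher calls was 25.2%, against 55.5% with quantile normalization, 55.5% with cyclic loess, 5.92% with normexp and 99.9% with scaling to the spike-in controls. The count fell to 0 without either smoke array, either EV array or both smoke arrays, to 0 with array weights, without the filter on dim probes and in a fit of the 2 groups only, and to 123 and 196 without MSC replicates 1 and 2. All 13 named genes called lost their call without either smoke array (highest adjusted p 0.0786), EV replicate 1 (0.268) or EV replicate 2 (0.150), and 9 did without MSC replicate 1 (0.127) or MSC replicate 2 (0.109). Without either naive array Slc17a6, Mcpt1, Cpa3 and Cd3e lost theirs (0.0587), and with quantile normalization Mcpt1, Tpsb2, Cpa3 and Cd3e (0.0783). Of the 5 list calls, 4 were lost without EV replicate 2. The immediate early and neutrophil calls were lost without MSC replicate 1, and the alveolar type 2, mast cell and T cell calls without MSC replicate 2. Normexp ended the immediate early, mast cell and neutrophil calls (0.242, 0.0803 and 0.221). The immediate early and mast cell calls were also lost with the mean of a gene's probes (0.0650 and 0.0514) and without the filter on dim probes (0.108), as were the alveolar type 2 call with the former (0.0546) and the T cell call with the latter (0.108). By fry 0 lists passed, with 1 at an unadjusted p under 0.05.

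Set against naive lung, EV-treated lung had 0 of 25097 features past limma's threshold, with 1069 at an unadjusted p under 0.05. The count was 0 with quantile normalization, normexp or cyclic loess, 2 with scaling to the spike-in controls, and 26 and 1 without naive replicates 1 and 2. By camera 7 lists were shifted, with 0 members past the threshold in any. The neutrophil list lay 0.82 log2 above the named genes (camera adjusted p = 0.000212, and adjusted p = 0.682 with an estimated correlation), with 1 member rising adjusted over the list alone. Its receptor gene Csf3r stood at 1.92 (SE 0.41, adjusted p = 0.951), on 1 of the 2 naive arrays. Also higher were heat shock genes (0.37, camera adjusted p = 0.00296, and adjusted p = 0.682 with an estimated correlation), such as Hsph1 at 1.49. The macrophage list (0.32, camera adjusted p = 0.0224, and adjusted p = 0.682 with an estimated correlation) held Cd163 at 1.26. The extracellular matrix list (0.25, camera adjusted p = 0.0161, and adjusted p = 0.682 with an estimated correlation) held the collagen chain gene Col5a1 at 1.15.

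The interferon list lay lower after EVs than in naive lung (-0.34, camera adjusted p = 0.00296, and adjusted p = 0.806 with an estimated correlation), with Ifi44 at -1.04. Scaling to the spike-in controls shifts all genes of a comparison alike, so its lower place there (camera adjusted p = 0.00153) is no separate support. On that scale its median was 0.099. Relative to the named genes, the immediate early list also lay lower than in naive lung (-0.52, camera adjusted p = 0.00463, and adjusted p = 0.888 with an estimated correlation), with Nr4a1 at -1.60. In these 5 lists 0 members passed adjusted over the list alone. By fry 0 lists passed, with 0 at an unadjusted p under 0.05. Leaving out naive replicate 1 ended 5 of the 7 list calls, naive replicate 2 ended 2, EV replicate 1 ended 4 and EV replicate 2 ended 3 (highest adjusted p 0.621, 0.501, 0.673 and 0.0575). The macrophage call was lost with quantile normalization (0.0545), and the macrophage and extracellular matrix calls with scaling to the spike-in controls (0.122 and 0.102).

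MSC-treated lung differed from naive lung in 1 feature by limma. This was Gpr158, lower by at least 2.65-fold (adjusted p = 0.0425), named after its values were seen. At an unadjusted p under 0.05 there were 5501 features. The count was 26 without naive replicate 1, 157 without MSC replicate 1, 0 with any 1 of the other arrays left out, 0 with the replicate number as a block, with array weights, without the filter on dim probes or in a fit of the 2 groups only, 161 with quantile normalization, 307 with normexp and 1599 with scaling to the spike-in controls. The alveolar type 2 list lay -0.83 log2 from the named genes (camera adjusted p = 0.00621, and adjusted p = 0.976 with an estimated correlation), with the phosphate transporter gene Slc34a2 at -1.29. Its median level was 2.06 on MSC replicate 2 but 3.21 on MSC replicate 1, near the naive 3.25 and 3.44. MSC replicate 2 stood apart from replicate 1 for other cell types as well, lower for alveolar type 1 cells (3.37 against 4.69) and higher for secretory (3.30 against -0.57), ciliated (1.98 against 0.21), cardiac muscle (1.34 against -2.08), B (-0.62 against -1.90) and T cells (-0.98 against -1.80). The fatty acid transporter gene Cd36 stood at -1.37, but its other probe at 1.04 and the mean of both at -0.16. The interferon list lay at -0.53 (camera adjusted p = 0.0359, and adjusted p = 0.976 with an estimated correlation), with Rtp4 at -1.81 and 2 members falling adjusted over the list alone. The cell cycle list lay higher, at 0.71 (camera adjusted p = 0.0127, and adjusted p = 0.976 with an estimated correlation), with the replication licensing gene Mcm3 at 1.497, whose other probe stood at 0.17. The class II list lay at 0.77 (camera adjusted p = 0.0215, and adjusted p = 0.976 with an estimated correlation), with RT1-DOb at 2.12. The T cell list lay at 0.56 (camera adjusted p = 0.0359, and adjusted p = 0.976 with an estimated correlation), with Cd4 at 1.25. Scaling to the spike-in controls shifts all genes of a comparison alike, so it could not change the place of these 3 lists relative to the other genes. Their camera adjusted p there (0.000232, 0.000156 and 0.00429) are thus no separate support. On that scale their medians were -0.22, -0.16 and -0.36. RT1-DOb and Cd4 were on 1 of the 2 naive arrays, and none of the named members passed. By fry 0 lists passed, with 1 at an unadjusted p under 0.05. Without MSC replicate 2 all 6 list calls were lost (adjusted p from 0.564 to 0.915) and the cell cycle list turned, without naive replicate 1, 3 were (up to 0.141), and without naive replicate 2, 2 (up to 0.402). The interferon call was lost with quantile normalization (0.0839) and cyclic loess (0.164), the class II and T cell calls under normexp (0.0627) and the T cell call without the filter on dim probes (0.0573).

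Cardiac muscle genes mark heart and the muscle sleeve of pulmonary veins. Their list lay 1.44 log2 above the named genes in EV-treated against naive lung (camera adjusted p = 0.00296, and adjusted p = 0.806 with an estimated correlation). In MSC-treated against naive lung it lay at 2.00 (camera adjusted p = 0.0193, and adjusted p = 0.976 with an estimated correlation). In both, 0 of 14 members passed by limma, with 0 and 1 adjusted over the list alone. Myh6, on 1 of the 2 naive arrays, stood at 4.71 (SE 2.89, adjusted p = 0.951) after EVs and 6.55 (SE 2.89, adjusted p = 0.238) after MSCs. Its level was 3.18 and -4.91 on the EV arrays, -2.22 and 4.16 on the MSC arrays, -7.45 and -3.71 on the naive arrays and -5.66 and -8.03 on the smoke arrays. The list median relative to all named genes was 2.47 and -1.62 on the EV arrays and -0.14 and 3.24 on the MSC arrays. It was -1.27 and -0.50 on the naive arrays and -2.67 and -2.11 on the smoke arrays. The EV call was lost, and its direction turned, without EV replicate 1 (adjusted p = 0.673). It was also lost without naive replicate 1 (0.233). The MSC call was lost without MSC replicate 2 (0.700) or naive replicate 1 (0.120).

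**Figure D4:**
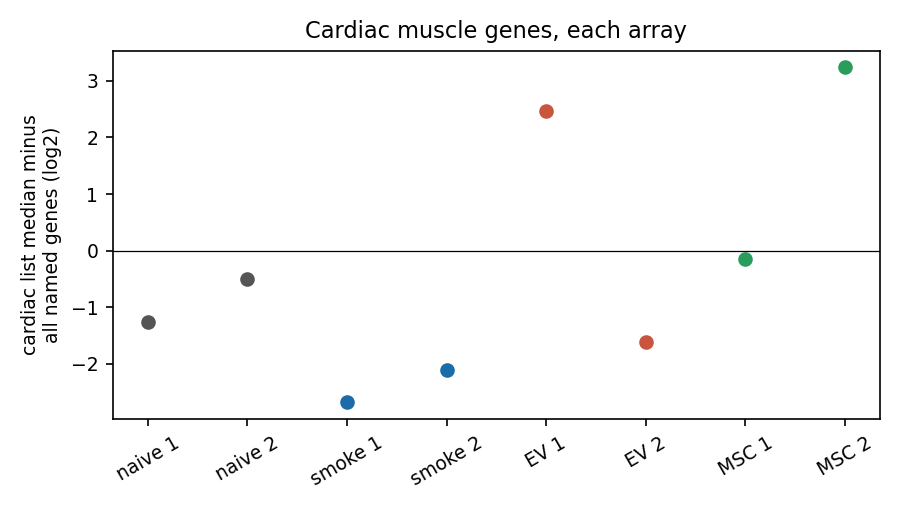
Median level of the 14 cardiac muscle genes on each array, minus the median of all named genes on that array (log2), coloured by group. EV replicate 1 (2.47) and MSC replicate 2 (3.24) stand above the other 6 arrays, which lie between -2.67 and -0.14.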

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

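The tests of the spike-in controls, ERCC probes, the directions of the EV and MSC effects, quantile normalization, receptor genes, likeness to the smoke arrays, the brightness gap and the cardiac genes were chosen only after the results they bear on were seen; those of 2 probes of a gene and of the shared smoke arrays were fixed before their values were computed, though counts of genes with probes called in opposite directions had been seen.

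The effects of EVs and MSCs, each against smoke, differed in 1791 features by limma's direct test. Among the named genes reported here, 24 differed (limma adjusted p from 0.0314 to 0.0496). The effect of EVs minus that of MSCs was positive for Gucy1b1 (3.73), Gpr158 (3.67), Gpm6a (3.57), C2cd2l (3.35), Fundc2 (3.25), Slfn4 (3.07), Vav3 (2.54), Cxcl1 (2.10), Lcn2 (2.09) and Il33 (1.55). It was negative for Suv39h2 (-3.53), Slc17a6 (-3.34), Ptprv (-3.03), Rnf43 (-3.00), Ephb2 (-2.64), Mcpt1 (-2.56), RT1-DOa (-2.55), Or9q1 (-2.31), Tpsb2 (-2.01), Cpa3 (-2.01), Ckm (-1.73), Mcm3 (-1.72), Cd3e (-1.64) and Foxm1 (-1.33), of which Foxm1 turned to 0.21 with scaling to the spike-in controls. On the percentile scale both effects had the same direction and that of MSCs was larger in 22 of the 24, with Mcpt1 and RT1-DOa running opposite ways, but with scaling to the spike-in controls this held in 15. Most of these genes were named for the size of a difference, so they are no sample of all genes. Gucy1b1, Gpr158, Gpm6a, C2cd2l, Fundc2, Slfn4 and Vav3 were not well above background after MSCs, Or9q1 and Slc17a6 in smoke, Slc17a6 after EVs, nor RT1-DOa after either treatment, so their values are fitted differences and not folds. Under normexp the EV minus MSC differences of Gucy1b1, Gpr158, Gpm6a and C2cd2l turned. With any 1 smoke or EV array left out the count was 0, and none of these calls held. Outside the gene probes, 2 of 96 probes for ERCC sequences were well above background on both MSC arrays and stood there at least 1 log2 above both naive arrays, in signal itself as well as on the percentile scale, ERCC-00018_67 by 2.72 log2 and ERCC-00113_271 by 2.89 on the latter. Other ERCC probes were higher on the percentile scale too. The 2 probes were at -10.08 and -8.99, and at -6.81 and -5.26, on the smoke arrays, against -3.25 and -3.59, and 0.16 and 0.16, on the naive arrays, and the ERCC-00018_67 level in smoke was not well above background.

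The smoke arrays were 6.49 times as bright as the naive arrays at the 75th percentile, and 47.5% of features were called between them. Stronger labelling or scanning of whole arrays is argued against by the spike-in controls, at -0.27 log2 in smoke against naive. These controls are RNAs of the array kit, so their own level does not show the amount or quality of the lung RNA, which was not tested. The labels give the same amount of RNA for labelling on every array. Relative to the controls, the 75th percentile stood at 0.63 and 0.067 log2 on the smoke arrays and -2.25 and -2.99 on the naive arrays. A difference in usable lung RNA thus stays open. A trend with intensity as the whole cause is argued against by quantile normalization, which left 9211 calls, 7937 of them shared. Effects of single probes may contribute, as the differences of 2 probes of a gene correlated across 1738 genes at 0.260 (95% interval 0.209 to 0.310). For 1 probe over separate pairs of arrays the correlation was 0.819. Of the 755 called genes among the 1738, 68.6% had both probes in the same direction. In EV against naive, where 0 features were called, the 2 probes correlated at 0.398. Signal without the named transcript on the dimmer arrays may contribute too, as the receptor genes lay at -1.38 relative to genes of like level (95% interval -1.52 to -1.19). Both 95% intervals come from resampling genes and hold no spread between arrays. Over the 6 arrays of the other groups, likeness to the smoke profile rose with brightness over the spike-in controls (Pearson r = 0.952, exact permutation p = 0.00278; Spearman rho = 0.943, exact permutation p = 0.0167; 1 relation tested; r = 0.934 without the 2 arrays farthest from the median), but these arrays are 3 groups of 2 that differ in both measures, and swaps within groups alone gave r = 0.711 and p = 0.25, the smallest they can give. Likeness and brightness also both use each array's 75th percentile, and the median smoke difference was negative on this scale. Part of the relation may thus be built in, so it cannot decide whether brightness is a cause. An effect of smoke on the lung stays open beside these possible causes.

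Both treatments ran against the smoke difference. Noise of single features on the shared smoke arrays is argued against as the whole cause by covariances of -1.67 for EVs and -2.28 for MSCs. Both lay below the lowest of 100 simulations of unchanged groups (-0.11 for each). The simulations drew features independently and held no departure common to a whole array, so they cannot speak to one. A tie to brightness cannot be told apart from an effect of the treatments: the dimmer smoke array lay 1.85 log2 above the brightest other array relative to the spike-in controls, so no groups matched for brightness could be compared. A reversal of smoke changes by either treatment may hold, as may a return of the arrays to the brightness of naive ones.

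The cardiac muscle list was shifted upward against naive lung after either treatment by camera, a call lost with an estimated correlation (adjusted p = 0.806 and 0.976), and 0 of its 14 members passed limma. Heart or pulmonary vein muscle in some of the lung pieces is a candidate source: the cardiac genes differed between the 2 MSC arrays by -3.73 log2, replicate 1 minus 2, with 13 of 14 higher in replicate 2, and between the EV arrays by 3.42, with 13 of 14 higher in replicate 1, against -0.48 and -0.32 in naive and smoke lung. MSC replicate 2 also stood above replicate 1 for secretory cell genes (3.30 against -0.57) and below it for alveolar type 2 genes (2.06 against 3.21), so what sets it apart is wider than cardiac genes. Whether treatment had a uniform effect on these genes cannot be told, as the arrays within each treated group differed by more than the list's shift from naive lung. EV replicate 2, at -1.62, lay below both naive arrays, while 3 of the 4 treated arrays lay above both. An uneven effect of treatment stays open.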

How the results depend on the processing

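Cyclic loess, scaling to the spike-in controls and leaving out both smoke arrays were chosen only after the results were seen; the other settings were planned. Of 170 results for named genes, tested in 2991 combinations with other settings, 2625 kept their direction and side of the threshold, 253 lost and 74 gained the call with the direction kept and 39 took the other direction. That tally leaves out the spike-in scaling, under which 120 of the 170 kept both, 7 lost and 21 gained the call and 22 took the other direction. Of the counts of genes and lists and the covariances, 144 values stayed within the set margin and 118 moved. RT1-CE5, Cyct, Or9q1, Cyp4a2 and Rela kept their calls in smoke against naive in every setting run on them. For those that fell, a kept call need not mean a change of transcript. On the percentile scale the ERCC-00113_271 probe, for a sequence that is not rat, differed by -6.19 log2, against -6.19 for Cyct and -6.31 for Or9q1. The replicate number as a block left 1004 genes called in EV against MSC and 0 in MSC against naive, with an excess covariance of -1.53 for EVs, and moved no other count by over 1.5 times. Same-numbered samples correlated between -0.15 and 0.14 after removing group means, which shows no strong pairing by number. The number is also the row of the slide, so a weak pairing stays possible. Except where fewer arrays or another number of features explains it, the cause was not tested.

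With normexp, genes called were 18511 in smoke against naive, 17225 in EV against smoke, 12642 in EV against MSC and 307 in MSC against naive, lists 8 in EV against smoke and 6 in MSC against smoke, and excess covariances -1.03 for EVs and -1.44 for MSCs. Directions turned for Gucy1b1 (-0.035), Gpr158 (-0.10), Gpm6a (-0.046), C2cd2l (-0.12) and Lpcat1 (-0.50) in EV against MSC, Mrc1 (-0.16), Csf3r (-0.041), Cyp1a1 (-0.67) and Ccl2 (-0.95) in smoke against naive, Cxcl10 (0.071), Klrk1 (0.48), Mmp12 (1.43), Tnf (0.12) and Ccl2 (0.48) in EV against smoke, Mmp9 (-0.18) in EV against naive and Cyp1a1 (1.31) in MSC against smoke.

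With quantile normalization, 161 genes were called in MSC against naive, lists were 0 in smoke against naive, 0 in EV against smoke and 1 in MSC against smoke, and excess covariances -1.35 and -1.97. Scgb1a1 turned in smoke against naive (0.39), EV against smoke (-0.55) and MSC against smoke (-1.28), Cyp1a1 in EV against smoke (-0.035), and Mmp12 (-0.50), Ccl2 (-0.21) and Sftpc (-1.07) in MSC against smoke. With cyclic loess, 0 lists were called in smoke against naive and 0 in EV against smoke, with excess covariances of -1.56 and -2.18. Prkcz (0.099 and -0.073) and Scgb1a1 (0.039 and -0.34) turned in smoke against naive and EV against smoke, Cyp1a1 (-0.36) in EV against smoke, and Mmp12 (-0.54), Ccl2 (-0.42) and Scgb1a1 (-0.86) in MSC against smoke. With scaling to the spike-in controls, genes called were 20888, 18560, 10243, 2 and 1599 in smoke against naive, EV against smoke, EV against MSC, EV against naive and MSC against naive, and lists 2, 2, 10 and 10 in smoke against naive, MSC against smoke, EV against MSC and MSC against naive.

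Without the filter on dim probes, 23325 genes were called in MSC against smoke, 0 in EV against MSC and 0 in MSC against naive, with 8, 6 and 2 lists in EV against smoke, MSC against smoke and EV against MSC and excess covariances of -1.23 and -1.86. With probes well above background on all 8 arrays, 3076 genes were called in EV against MSC and 66 in MSC against naive, with 2 lists in smoke against naive and 2 in EV against MSC and excess covariances of -1.33 and -1.92. With the mean of a gene's probes, lists were 0 in EV against smoke and 2 in EV against MSC, excess covariances -1.49 and -2.07, and Prkcz turned in smoke against naive (0.69) and EV against smoke (-0.73). Fits of only the 2 groups compared, array weights and leaving out both smoke arrays each gave 0 genes in EV against MSC and 0 in MSC against naive, where the trended and robust prior gave 69 in MSC against naive. With an estimated correlation, 0 lists were called in each comparison, and with fry 1, 1, 2, 0, 0 and 0 in smoke against naive, EV against smoke, MSC against smoke, EV against MSC, EV against naive and MSC against naive. With separate smoke arrays for the 2 effects, covariances were -1.57 and -1.57 for EVs and -2.21 and -2.16 for MSCs.

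With each array left out in turn, genes called ranged from 4376 to 13288 in smoke against naive, 1860 to 11505 in EV against smoke, 10119 to 15115 in MSC against smoke, 0 to 1748 in EV against MSC, 0 to 26 in EV against naive and 0 to 157 in MSC against naive. Lists ranged from 2 to 8, 0 to 3, 0 to 10, 1 to 11, 4 to 10 and 1 to 12 in the same order, and excess covariances from -1.85 to -1.05 for EVs and -2.48 to -1.64 for MSCs. Directions turned within the ranges of Mmp12 (-3.71 to 0.44) and Ccl2 (-0.028 to 1.58) in smoke against naive, Mmp12 (-1.55 to 0.17) and Cyp1a1 (-1.90 to 2.72) in EV against smoke, and Ccl2 (-0.21 to 1.31) and Scgb1a1 (-0.54 to 1.39) in MSC against smoke. Fewer arrays leave fewer degrees of freedom, and signal over background limited detection to between 48.1% and 71.3% of probes per array.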

Other observations

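The spike-in scaling and the levels per array were chosen only after the results were seen, as were the lists given here, for their counts; their tests were fixed beforehand. In smoke against naive, 4 of 22 rose and 6 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.836), among the genes that answer to the antioxidant regulator NRF2. In the xenobiotic metabolism list, 3 of 15 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.492). Among proteases, cathepsins and their inhibitors, 5 of 22 rose and 2 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.195). In cholesterol synthesis, 2 of 18 rose and 6 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.872). Among T cell genes, 1 of 17 rose and 6 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.845). Among alveolar type 2 cell genes, 2 of 15 rose and 4 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.960). With quantile normalization, rising and falling members of these 6 lists were 7 and 3, 5 and 2, 8 and 0, 3 and 3, 3 and 3 and 3 and 0 in the same order, so the balance turned for the NRF2 and alveolar type 2 lists. With scaling to the spike-in controls they were 21 and 0, 15 and 0, 20 and 0, 17 and 0, 14 and 0 and 13 and 0, and 99.4% of all calls in this comparison were higher.

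In MSC against smoke, no list of cell types given here passed camera. Among mast cell genes, 8 of 13 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.203). Among secretory and goblet cell genes, 6 of 12 rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.353). Among endothelial genes, 4 of 20 rose and 7 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.203). Among ciliated cell genes, 5 of 11 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.355). In the same order, rising and falling members were 4 and 1, 3 and 0, 3 and 11 and 3 and 0 with quantile normalization, and 0 and 12, 0 and 6, 0 and 20 and 0 and 11 with scaling to the spike-in controls, where the direction turned for the mast, secretory and ciliated cell lists. The MSC arrays differed: the median level of the secretory list was -0.57 on replicate 1 and 3.30 on replicate 2, against -1.66 and -1.85 on the smoke arrays, and that of the ciliated list 0.21 and 1.98, against -0.29 and -0.35. The median of all features lay at 0.74 log2 in that comparison, and with scaling to the spike-in controls it turned to -3.28, with 197 features called higher and 22069 lower.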
